A study of Homo sapiens with 6 samples.

How the data were processed

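RNA from KMM1 cells was profiled in 6 libraries: 3 libraries from cells transduced with lentivirus expressing TAZ and 3 from cells transduced with the empty vector WPI. Per the labels' protocols, RNA was taken 4 days after transduction, samples with an RNA integrity number above 8 were kept, polyadenylated RNA was enriched from 15 ug of total RNA, spike-in RNA was added, RNA was fragmented with RNase III, and libraries were sequenced on an Ion Torrent Proton instrument with 2 libraries per chip. Which libraries shared a chip is not given in the sources used here, so chip and group could not be separated or checked. The spike-in values were not used here. Groups and replicate numbers came from the labels.

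Per the submitters' processing notes, reads were mapped to hg19 with STAR 2.3.0 and Bowtie2 2.0.0 and quantified with StringTie 1.3.3b. Per the file headers, StringTie ran with a supplied annotation and estimated only its transcripts, 1 run per library, with no pooling. The release of that annotation is not given in the sources used here, nor is the use of strand in the assignment of reads. The deposited values are coverage (mean read depth per base, for each transcript and each exon), FPKM (coverage relative to the total of aligned bases of the library) and TPM (coverage relative to the sum over all transcripts of the library), for 195984 transcripts of 57290 genes. No read counts were used, and tests made for counts were not run. Transcript TPM deposited by the authors was summed over the transcripts of each gene. The total of aligned bases in each library was recovered from the ratio of the deposited coverage to the deposited FPKM, which is constant within a library. It was 1719, 2033 and 1099.95 megabases in control libraries 1, 2 and 3, and 1608, 1130.4 and 1230.05 megabases in TAZ libraries 1, 2 and 3. Between 73.6% and 75.9% of these bases lay on annotated transcripts. StringTie spreads reads shared by near-identical sequences over genes, so values of paralogs, pseudogenes and overlapping genes are less certain than the SD between libraries shows.

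TPM was scaled between libraries by the median of ratios to the geometric mean over the libraries, computed on the 28148 genes above 0 in every library. The factors were 0.994, 0.944 and 0.873 for the control libraries and 0.962, 1.20 and 1.23 for the TAZ libraries. Genes with a mean of at least 1 TPM (19390) were tested on log2(scaled TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust), TAZ against control, without a block, and p was adjusted with the Benjamini-Hochberg method over all tested genes at a threshold of 0.05. A fold change on this scale understates the change of genes with low TPM. Levels are given as mean ± SD of scaled TPM over n = 3 libraries per group, and log2 differences as TAZ minus control ± SE.

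The procedure was tested on simulated data with the means and the limma moderated spreads of these 19390 genes, of which 200 were changed. The simulated noise was normal, independent between genes and of equal spread in both groups. The 200 were drawn from the more abundant genes only, so recovery at low TPM was not measured. The procedure recovered 15% of 100 genes changed 2-fold and 86% of 100 genes changed 4-fold. It made 0 calls of the wrong sign and 8 calls among unchanged genes. With no gene changed it called 0. The simulated data follow the model that was tested, so these counts do not give the rate of false calls in the real libraries. The median SE over the tested genes was 0.24 on the log2 scale, so changes under 2-fold were mostly below what these libraries could resolve.

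The gene lists were written before the data were examined, 27 in all, as were the tests and most alternatives. They cover YAP/TAZ targets, the Hippo pathway, MYC targets, cytosolic ribosomal proteins, G1/S and G2/M cell cycle genes, apoptosis, p53 targets, interferon response, NF-kB and TNF response, immediate early genes, plasma cell identity, B cells, the unfolded protein response, the ATF4 amino acid response, glycolysis and hypoxia, nuclear oxidative phosphorylation, cholesterol biosynthesis, cytoskeleton and SRF targets, extracellular matrix and adhesion, myeloma drivers and drug targets, epithelial or packaging line cells, fibroblasts and stroma, T and NK cells, myeloid cells, mitochondrially encoded genes and replication histones. Each list with at least 3 tested members (26) was compared with all other tested genes by camera (limma) with a preset correlation of 0.01 between members and Benjamini-Hochberg adjustment over the lists. Beside it stand camera with an estimated correlation, and fry (limma), which asks only whether a list's own members move one way on balance. The median log2 difference of each list was also placed among 10000 random lists of equal size, matched on mean expression in 40 bins. Members are counted at adjusted p under 0.05 over all tested genes and, where stated, adjusted over the list alone.

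The genes named in the results were set by a rule fixed beforehand. It takes 7 genes in every case (WWTR1, MYC, CYR61, CTGF, ANKRD1, YAP1 and the gene with the symbol TAZ), the 10 higher and 10 lower genes with the largest log2 difference among those past the threshold with no overlap between groups, a mean of at least 5 TPM in the higher group and a unique ordinary symbol, and up to 4 tested members of each list with the smallest p. Some genes that the rule takes are not reported here. Other genes are said to be chosen after their values were seen. Symbols and coordinates (hg19) are those of the deposited files. Gene types came from GENCODE 29 by gene identifier, which matched 51824 of the 57290 genes (90.5%), and the coding part of WWTR1 exons from the same release by transcript identifier and exon length; no coordinates were taken from it. Exons shared between genes were found with bedtools 2.31.1. For WWTR1, the deposited exon coverage was compared between groups with an exact two-sided permutation test, whose smallest possible p with 3 against 3 libraries is 0.1. Other calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

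Alternatives set beforehand were no scaling, quantile normalization, FPKM in place of TPM, pseudocounts of 0.1 and 0.5, no filter, a filter at a mean of 5 TPM, rescaling without immunoglobulin genes, mitochondrial genes and WWTR1, eBayes without trend and robust, leaving out each library, and the replicate number as a block. Added after seeing the data were factors from the tested genes, cyclic loess normalization and protein-coding genes only. For WWTR1 exon coverage, division by aligned bases and leaving out each library were tried.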

Results

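KMM1, an established human multiple myeloma cell line, was compared between cells transduced with a lentivirus expressing TAZ and cells that received the empty vector. TAZ is a transcriptional co-activator at the end of the Hippo pathway that acts through TEAD transcription factors; its gene is WWTR1. The comparison asks which transcripts change when TAZ is restored to a myeloma line, and the level of MYC, an oncogene active in much of this disease, is of particular interest. Polyadenylated RNA was measured 4 days after transduction in 3 control and 3 TAZ libraries. The libraries held between 1099.95 and 2033 megabases of aligned sequence, with a mean of 1617 ± 475 megabases in the controls and 1323 ± 252 megabases in the TAZ libraries (SD, n = 3). Correlations between libraries over log2(scaled TPM + 1) ran from 0.878 to 0.948, and the first principal component, with 38.9% of the variance, placed all 3 TAZ libraries on one side of the 3 controls. Control library 3 stood apart: it lay at -74.8 on the second component (23.4% of the variance), against 3.70 and 37.6 for the other controls, and correlated at 0.926 with control library 2, at 0.918 with TAZ library 1 and at 0.897 with control library 1. Without it 765 genes and 12 lists were called, against 623 and 19 with all libraries. The labels do not say that the libraries came from separate cultures, so p-values measure the spread between these samples, which may be technical.

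WWTR1 (ENSG00000018408.10, chromosome 3, 149235022 to 149454501, minus strand, hg19) rose from 1.65 ± 0.609 scaled TPM in the controls to 216 ± 129 in the TAZ libraries, a log2 difference of 6.22 ± 0.41 (limma adjusted p = 8.35e-04). The transcript ENST00000465804.1 held 99.78% to 99.91% of the WWTR1 bases in the TAZ libraries and 11.002% to 21.2% in the controls, where most of the remainder lay on an exon of ENST00000474080.1 (149419392 to 149420745). Over the internal coding exons of ENST00000465804.1 (exons 2 to 6 when counted from the lowest coordinate, 1021 bases, of which 1018 are coding), read depth was 1464, 427 and 516 in the TAZ libraries and 0.410, 0 and 0 in the controls. The means were 802 ± 575 and 0.137 ± 0.237 (n = 3; exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow). Exon 1 (149235022 to 149238776), which is 3′ untranslated apart from 182 of its 3755 bases, had a depth of 0.116 ± 0.0359 in the TAZ libraries and 0.104 ± 0.0599 in the controls (n = 3; exact permutation p = 0.8), and the untranslated exons 7 and 8 were listed at 0 in every library. Within the coding part the depth was uneven: exon 4 (149260122 to 149260324) had 2196 ± 735 and exon 6 (149374663 to 149375096) 765 ± 1091 in the TAZ libraries, exon 2 was above 0 in TAZ library 3 alone, and exons 3 and 5 were listed at 0. The gene with the symbol TAZ in the files is tafazzin (X chromosome), a mitochondrial acyltransferase unrelated to the transgene. It had 20.8 ± 1.65 scaled TPM in the controls and 26.7 ± 4.46 in the TAZ libraries (limma adjusted p = 0.374). YAP1, the paralog of WWTR1, had 4.41 ± 0.342 and 5.40 ± 1.21 (adjusted p = 0.575).

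**Figure D1:**
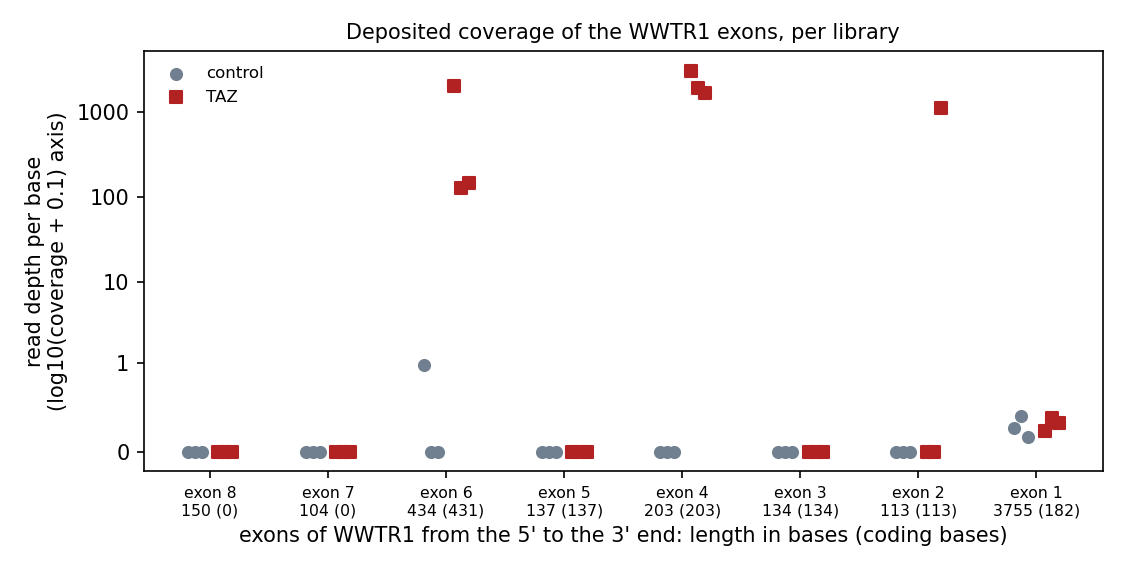
Deposited read depth per base (y axis, log10 of coverage plus 0.1) of the 8 exons of the WWTR1 transcript ENST00000465804.1, drawn from the 5′ to the 3′ end, with a circle for each of the 3 control and a square for each of the 3 TAZ libraries. Signal in the TAZ libraries lies in the coding exons 6 and 4, and in exon 2 for TAZ library 3 alone, while coding exons 3 and 5 are at 0. Exon 1, which holds the 3′ untranslated region and 182 coding bases, stays near 0.1 in both groups. Exons without signal thus do not separate untranslated from coding sequence.

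Of 19390 tested genes, 623 (3.21%) passed an adjusted p of 0.05 (limma, Benjamini-Hochberg): 436 were higher and 187 lower in the TAZ libraries. Without scaling between libraries the split was 533 higher and 85 lower, and the median log2 difference of all tested genes moved from -0.05 to 0.17. Changes of at least 4-fold on the log2(TPM + 1) scale were found for 180 higher and 32 lower genes, and 461 of the called genes were protein-coding. All 623 showed no overlap between the 3 TAZ and the 3 control libraries. Over all tested genes 24.9% showed none, against 10% by chance. With any 1 of control library 1, control library 2, TAZ library 2 or TAZ library 3 left out, the count was 409, 349, 270 and 337.

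The genes that rose most were led by targets of YAP and TAZ. ANKRD1 (ENSG00000148677.6, chromosome 10, 92671853 to 92681033), a TEAD-dependent cardiac ankyrin repeat protein, went from 0.0885 ± 0.105 to 232 ± 16.5 scaled TPM, a log2 difference of 7.74 ± 0.16 (limma adjusted p = 2.08e-05). CYR61 (ENSG00000142871.11, chromosome 1, 86046444 to 86049645), a secreted matrix-associated protein, went from 2.00 ± 1.16 to 447 ± 30.8 (7.29 ± 0.28, adjusted p = 1.69e-04). The remaining 8 of the 10 largest increases were WWTR1, DKK1, TMEM189-UBE2V1, AMOTL2, LUM, AKR1C3, HBEGF and LYPD5. DKK1, a secreted Wnt antagonist linked to bone disease in myeloma, reached 79.7 ± 7.405 from 0.622 ± 0.157. HBEGF, a ligand of the EGF receptor, reached 71.6 ± 3.01 from 1.39 ± 0.127, and AKR1C3, an aldo-keto reductase, 40.9 ± 13.7 from 0.350 ± 0.394. TMEM189-UBE2V1 is a read-through transcript whose exons are shared with TMEM189 and UBE2V1, so its increase from 2.74 ± 2.56 to 132 ± 7.90 depends on how reads were assigned; neither of the partner genes passed the test.

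Among the 10 largest decreases were the chemokine genes CCL3L1, CCL3L3 and CCL4 and the chemokine receptor gene CCR3. CCL3L1 fell from 217 ± 76.1 to 22.5 ± 4.57 scaled TPM (limma log2 difference -3.17 ± 0.31, adjusted p = 0.00353) and CCL3L3 from 149 ± 46.0 to 16.3 ± 2.49; both are near-identical copies that share reads with each other and with CCL3, which was 196 ± 131 and 58.5 ± 7.33 (adjusted p = 0.182). CCR3 fell from 33.9 ± 10.9 to 3.67 ± 1.25. AQP3, a water and glycerol channel, fell from 69.5 ± 10.1 to 9.01 ± 0.787, KCNA3, a lymphocyte potassium channel, from 23.6 ± 4.56 to 3.17 ± 0.174, and the immunoglobulin segment IGLV6-57 from 63.5 ± 7.30 to 10.1 ± 1.00. NDUFA5 and COX7A2, subunits of respiratory complexes I and IV, fell from 19.0 ± 2.37 to 0.626 ± 0.378 and from 113 ± 29.5 to 12.5 ± 5.60. Both have processed pseudogenes in the annotation with signal: NDUFA5P11 was 50.7 ± 9.14 and 26.8 ± 2.79, and COX7A2P2 64.8 ± 19.1 and 35.1 ± 8.26 (limma adjusted p = 0.0677 and 0.198). In the TAZ libraries each pseudogene stood above its parent gene, so the size of these falls may depend on how reads were assigned. TMEM11, a mitochondrial inner membrane protein, fell from 53.1 ± 3.34 to 3.86 ± 0.420.

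**Figure D2:**
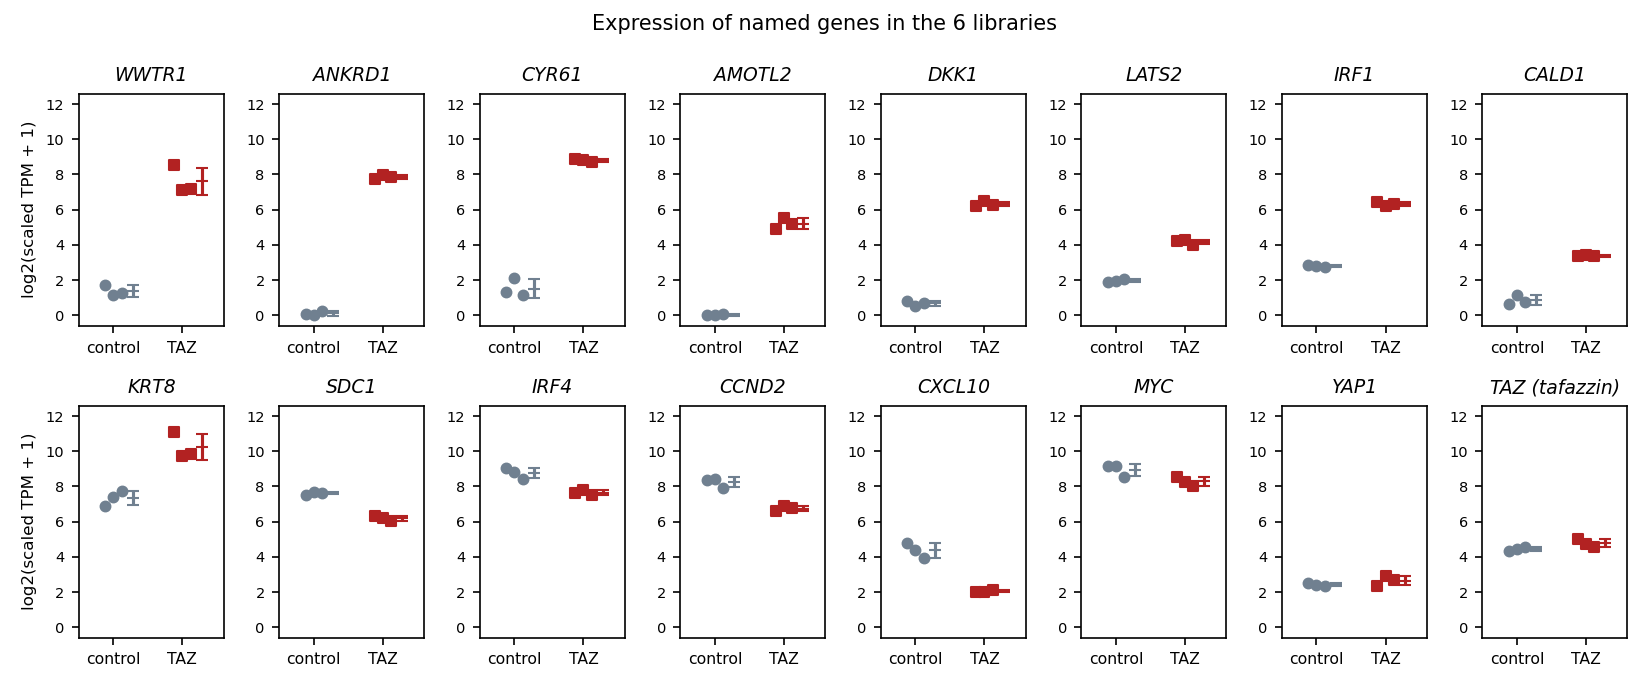
Level of 16 named genes as log2(scaled TPM + 1) (y axis) in the 3 control libraries (circles) and the 3 TAZ libraries (squares); the bars beside the points give mean ± SD. WWTR1 averaged 1.65 and 216 scaled TPM in control and TAZ libraries and MYC 503.8 and 315; the last panel is tafazzin, whose symbol is TAZ.

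YAP and TAZ target genes rose together. Of 22 listed, 14 were abundant enough to be tested, in part through the rise itself, and of these 8 rose and 0 fell. Their median log2 difference was 2.25, above all 10000 matched random lists, and 0.59 with no filter on abundance; adjusted over the list alone, 11 rose and 2 fell. Besides ANKRD1 and CYR61, AMOTL2, a Hippo regulator of the angiomotin family, went from 0.0192 ± 0.0333 to 36.6 ± 7.67 scaled TPM and TGFB2, a TGF-beta ligand, from 0.162 ± 0.0604 to 14.8 ± 2.04. CTGF, a classical TAZ target, was not tested: it was listed at 0.00794, 0 and 0 in the controls and at 0.150, 0.188 and 0.148 in the TAZ libraries. Of 22 tested Hippo pathway genes, 3 rose and 0 fell, over all genes as well as adjusted over the list alone. They were AMOTL2, AMOT (0.0298 ± 0.0339 to 2.37 ± 0.384) and the kinase LATS2 (2.94 ± 0.205 to 16.9 ± 1.53), which phosphorylates and inhibits YAP and TAZ. AMOTL2 and LATS2 are also on the list of targets, so the Hippo call is not separate evidence. The camera adjusted p was 3.16e-14 for the targets (0.0275 with an estimated correlation) and 0.0114 for the Hippo list, whose median was 0.09 (adjusted p = 0.264 with an estimated correlation). Without control library 3 the Hippo list was no longer called.

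The interferon response list was called higher. Of 23 tested genes, 8 rose, among them IRF1, IFI27, IFI6, STAT2, IFIT5, IFI35 and XAF1, and 0 fell, with a median log2 difference of 0.79, or 0.51 with no filter on abundance; adjusted over the list alone, 11 rose and 0 fell. The transcription factor IRF1 went from 5.998 ± 0.321 to 79.3 ± 6.87 scaled TPM (limma adjusted p = 2.28e-04), and the interferon-induced gene IFI27 from 0.151 ± 0.140 to 7.55 ± 1.55. The list had a camera adjusted p of 9.92e-12 (adjusted p = 0.143 with an estimated correlation). The list of NF-kB and TNF response genes was called lower: of 19 tested, 0 rose and 2 fell, the chemokines CXCL10 (20.3 ± 5.94 to 3.15 ± 0.138) and CCL4 (6.51 ± 1.81 to 0.439 ± 0.146). Adjusted over the list alone 0 rose and 5 fell. The median was -0.54, or -0.32 without scaling (camera adjusted p = 9.55e-04; adjusted p = 0.241 with an estimated correlation). CXCL10 is induced by interferon as well as by NF-kB. ICAM1, an adhesion molecule, was 368 ± 95.4 in controls and 157 ± 45.7 in TAZ libraries (limma adjusted p = 0.0968). Among 17 tested immediate early genes, 3 rose and 1 fell: the AP-1 subunits FOSL2 (2.86 ± 0.870 to 19.6 ± 2.44) and FOSL1 (1.63 ± 0.228 to 5.77 ± 0.259) and IER2 (5.67 ± 3.23 to 58.1 ± 6.01) were higher, and KLF2, a transcription factor of quiescent lymphocytes, was lower (10.7 ± 0.403 to 2.60 ± 0.960). Adjusted over the list alone 4 rose and 1 fell. The median was 0.28 (camera adjusted p = 0.0133; adjusted p = 0.448 with an estimated correlation), and the call was lost without control library 3 and without TAZ library 1.

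The plasma cell identity list was called lower. Of 17 tested genes, 5 fell (IRF4, SDC1, SLAMF7, ELL2 and SEC11C) and 1, DERL3, rose; adjusted over the list alone, 7 fell and 2 rose. SDC1, the plasma cell surface proteoglycan CD138, went from 197 ± 9.97 to 72.6 ± 7.05 scaled TPM (limma log2 difference -1.43 ± 0.16, adjusted p = 0.00521). ELL2, an elongation factor that promotes secretory immunoglobulin mRNA, went from 105 ± 2.68 to 42.6 ± 3.92. DERL3, a factor of endoplasmic reticulum-associated degradation, went from 10.1 ± 2.92 to 40.5 ± 2.55. The list had a median log2 difference of -0.69, or -0.44 without scaling (camera adjusted p = 0.00714; adjusted p = 0.143 with an estimated correlation). Of 26 tested myeloma drivers and drug targets, 4 fell and 0 rose (5 and 1 adjusted over the list alone), and the list as a whole was not called (median -0.14, camera adjusted p = 0.124). The genes that fell were IRF4, a transcription factor on which myeloma cells depend (443 ± 89.9 to 200.3 ± 19.2), CCND2, a cyclin D (305 ± 54.1 to 107 ± 10.99), SLAMF7, the target of elotuzumab (175 ± 53.3 to 55.1 ± 7.96), and FAM46C, a poly(A) polymerase mutated in myeloma (28.4 ± 7.80 to 6.45 ± 0.961). IRF4 and SLAMF7 were each called in 9 of 19 other settings, and without scaling between libraries neither passed. Of 8 tested B cell genes only BACH2, a repressor of plasma cell differentiation, passed; it rose from 5.33 ± 0.412 to 12.1 ± 1.78, while HLA-DRA was 161 ± 46.0 and 80.1 ± 0.722 (limma adjusted p = 0.0846). Adjusted over the list alone, 1 rose and 1 fell (list median -0.39, camera adjusted p = 0.273).

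Lists of secretory and amino acid stress genes were called lower. Of 23 tested genes of the unfolded protein response, 0 rose and 2 fell, with equal counts adjusted over the list alone: HERPUD1, an endoplasmic reticulum degradation factor (285 ± 41.8 to 103 ± 15.6 scaled TPM), and ERN1, the stress sensor IRE1 (26.7 ± 3.32 to 11.7 ± 0.727). The median was -0.22 (camera adjusted p = 0.0421; adjusted p = 0.264 with an estimated correlation). It was 0.03 without scaling and lay at percentile 30.6 of the matched random lists, so it was ordinary for genes of that expression, and the call was lost in 8 of 19 other settings. Of 21 tested ATF4 amino acid response genes, 0 rose and 3 fell: CEBPB, a leucine zipper factor (64.8 ± 3.51 to 32.6 ± 1.08), ASNS, asparagine synthetase (279 ± 28.01 to 148 ± 6.94), and SLC7A5, an amino acid transporter (259 ± 35.05 to 111 ± 26.8). Adjusted over the list alone, 1 rose and 3 fell, and the median was -0.49 (camera adjusted p = 0.00511; adjusted p = 0.264 with an estimated correlation); the call was lost without control library 3. ASNS was called in 8 of the 19 other settings, ERN1 in 11, CEBPB and SLC7A5 in 12; without scaling ASNS, ERN1 and CEBPB did not pass.

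MYC (ENSG00000136997.10, chromosome 8, 128747680 to 128753674) was lower in each TAZ library than in any control library, at 315 ± 55.4 against 503.8 ± 109.7 scaled TPM, but did not pass the test (limma log2 difference -0.66 ± 0.24, adjusted p = 0.231). The nearest libraries, control library 3 and TAZ library 1, stood at 377 and 375. It was not called in any of 19 other settings, in which the log2 difference lay between -0.87 and -0.40 and the adjusted p between 0.0885 and 0.536. Of 57 tested MYC targets, 0 rose and 0 fell, over all genes and adjusted over the list alone. Their median log2 difference was -0.35, 45 of the 57 were below 0, and the median lay at percentile 0.15 of the matched random lists. The list was called lower (camera adjusted p = 8.39e-04; adjusted p = 0.264 with an estimated correlation), also in 19 of 19 other settings, but the size depends on the scaling: without it the median was -0.11. Examples were SRM, spermidine synthase, at 183 ± 16.7 and 93.6 ± 32.6 (limma adjusted p = 0.112), and TCOF1, a nucleolar factor of ribosomal RNA transcription, at 57.0 ± 8.82 and 30.3 ± 6.47 (adjusted p = 0.0902). Over the 1296 tested genes with a mean of at least 100 TPM the median log2 difference was -0.25. None of the 60 tested cytosolic ribosomal protein genes passed, nor did the list (median -0.26, camera adjusted p = 0.189); the examples went both ways, with RPS9 at 296 ± 57.5 and 156 ± 7.28 and RPS19 at 109 ± 42.9 and 331 ± 135 (limma adjusted p = 0.0751 and 0.0874).

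The 2 cell cycle lists were called lower while few genes passed individually, and without scaling their medians shrank to -0.15 for G1/S and -0.14 for G2/M. Of 25 tested G1/S genes, 1 fell, CCND2, and 0 rose; adjusted over the list alone, 5 fell and 0 rose (median -0.41, camera adjusted p = 0.00305; adjusted p = 0.245 with an estimated correlation). Of 26 tested G2/M genes 0 rose and 0 fell, and adjusted over the list alone 4 fell and 0 rose (median -0.37, camera adjusted p = 9.55e-04; adjusted p = 0.143 with an estimated correlation). TPX2, a spindle assembly factor, was 104 ± 14.2 and 54.5 ± 8.51 scaled TPM, and AURKA, the mitotic kinase it activates, 103 ± 12.7 and 62.4 ± 5.71 (limma adjusted p = 0.0631 and 0.0946). Among 28 tested apoptosis genes, 1 rose, BCL2L11, the pro-apoptotic protein BIM (25.7 ± 9.25 to 85.2 ± 11.8), and 0 fell; adjusted over the list alone, 1 rose and 2 fell (median -0.10, camera adjusted p = 0.953). BCL2L1, the anti-apoptotic protein BCL-XL, was 184 ± 23.2 and 104 ± 12.8 (limma adjusted p = 0.0772). Among 23 tested p53 targets only CDKN1A, the cyclin-dependent kinase inhibitor p21, passed, with a rise from 5.39 ± 0.238 to 14.7 ± 3.23, also adjusted over the list alone (median -0.17, camera adjusted p = 0.891).

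Metabolic lists were called lower, with few genes passing individually. Of 24 tested glycolysis and hypoxia genes, 2 fell, GPI, glucose-6-phosphate isomerase (271 ± 53.5 to 69.6 ± 32.8 scaled TPM), and the aldolase ALDOC (45.9 ± 4.04 to 18.4 ± 5.81; called in 7 of 19 other settings), and 1 rose, the glucose transporter SLC2A3 (6.56 ± 1.99 to 39.3 ± 2.85). Adjusted over the list alone, 4 fell and 1 rose; the median was -0.50 (camera adjusted p = 0.0150; adjusted p = 0.264 with an estimated correlation), and the call was lost at a minimum of 5 TPM. Of 24 tested cholesterol biosynthesis genes, 1 fell and 0 rose; adjusted over the list alone, 5 fell and 0 rose. SQLE, squalene epoxidase, was 49.5 ± 13.2 and 24.5 ± 0.864 (limma adjusted p = 0.0795). The list was called lower (median -0.33, or -0.09 without scaling, camera adjusted p = 0.00913; adjusted p = 0.264 with an estimated correlation). None of 29 tested nuclear genes of oxidative phosphorylation passed, over all genes or adjusted over the list alone; their median was -0.26, at percentile 25.7 of the matched random lists (camera adjusted p = 0.00913; adjusted p = 0.340 with an estimated correlation; fry adjusted p = 0.0507), and the call was lost with quantile normalization, with cyclic loess and without control library 3. COX4I1, a subunit of complex IV, was 174 ± 4.74 and 101 ± 11.6 (limma adjusted p = 0.0593). All 13 tested mitochondrially encoded genes had a log2 difference below 0 and 0 passed, over all genes or adjusted over the list alone (median -0.31, at percentile 40.4 of the matched random lists, camera adjusted p = 0.0151; adjusted p = 0.526 with an estimated correlation; fry adjusted p = 0.161). The list was called in 11 of 18 other settings, and its direction turned with quantile normalization, where the median was 0.08, and with cyclic loess, where it was 0.06. None of 12 tested replication histone genes passed (median -0.18, camera adjusted p = 0.419).

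The cytoskeletal list was called higher. Of 23 tested cytoskeleton and SRF target genes, 7 rose, among them CALD1, MYL9, VCL, ACTN4, TPM4 and CNN2, and 0 fell, with a median log2 difference of 0.73; adjusted over the list alone, 12 rose and 1 fell. CALD1, an actin- and myosin-binding protein, went from 0.829 ± 0.362 to 9.44 ± 0.403 scaled TPM (limma adjusted p = 0.00157), and MYL9, a myosin light chain of contractile cells, from 0.947 ± 0.947 to 34.0 ± 12.3. The list had a camera adjusted p of 1.51e-08 (adjusted p = 0.143 with an estimated correlation). Among 17 tested matrix and adhesion genes, 1 rose, the integrin ITGB7 (160 ± 49.7 to 865 ± 417), and 1 fell, the adhesion molecule VCAM1 (8.05 ± 1.31 to 1.31 ± 0.0938); adjusted over the list alone, 4 rose and 3 fell. The median was 0.44, or 0.24 with no filter (camera adjusted p = 0.0312; adjusted p = 0.241 with an estimated correlation), and the call was lost without scaling, without control library 2 and without control library 3.

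Markers of cell types other than plasma cells were examined in these cultures too. Of 9 tested markers of epithelial or packaging line cells, 3 rose and 0 fell (3 and 1 adjusted over the list alone): the keratins KRT8 (167 ± 45.5 to 1337 ± 762 scaled TPM) and KRT18 (0.283 ± 0.290 to 12.7 ± 3.93) and the tight junction protein CLDN4 (3.36 ± 0.836 to 13.002 ± 3.35). KRT8 and KRT18 have exons that overlap each other on opposite strands and have 50 and 62 pseudogenes in the annotation. CDH1, E-cadherin, was 48.7 ± 10.5 and 25.2 ± 7.08 (limma adjusted p = 0.161). The list had a median of 0.40, or 0.14 with no filter (camera adjusted p = 0.00714; adjusted p = 0.241 with an estimated correlation). Of 10 listed fibroblast markers 3 were tested, and 2 of them rose, over all genes and adjusted over the list alone, the matrix proteoglycans LUM (0.102 ± 0.105 to 35.1 ± 3.53) and DCN (0.113 ± 0.103 to 3.39 ± 0.307), while the collagen COL1A1 was 1.79 ± 0.320 and 1.73 ± 0.220 (limma adjusted p = 0.949; list median 1.98, camera adjusted p = 6.70e-04; adjusted p = 0.143 with an estimated correlation). LUM and DCN were abundant enough to be tested only through the TAZ libraries, and with no filter the median of the list was 0.04. Of 3 tested T and NK cell genes 0 passed (median 0.16, camera adjusted p = 0.471). The myeloid marker CD14, the sole tested member of its list, fell from 4.23 ± 0.866 to 1.51 ± 0.213 (adjusted p = 0.0435) and was called in 8 of 18 other settings.

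Of the 26 lists tested, camera called 19 (8 higher and 11 lower) with the preset correlation and 1, the YAP and TAZ targets, with an estimated correlation. Some called lists share genes, such as AMOTL2, LATS2 and ICAM1, so the calls are not all separate. Fry called 15 of the 19, all but the lists of immediate early, glycolysis, nuclear oxidative phosphorylation and mitochondrially encoded genes (adjusted p = 0.0783, 0.0512, 0.0507 and 0.161). The Hippo median lay at percentile 92.6 of the matched random lists. The median, the mean and the direction of the camera test had the same sign in each of the 26 lists. The sign of the median turned with at least 1 other scaling for the lists of ribosomal proteins, apoptosis, p53 targets, the unfolded protein response, myeloma drivers, mitochondrially encoded genes and histones. Without scaling the median of the glycolysis list was -0.28, of the ATF4 list -0.24, of the nuclear oxidative phosphorylation list -0.03, of the Hippo list 0.34 and of the immediate early list 0.52. Besides the genes given with such counts, BCL2L11, BACH2 and VCL were called in 12 of the 19 other settings, CDKN1A, GPI and ITGB7 in 13 and KLF2 and CLDN4 in 14. Exons of several genes named above overlap exons of another gene, and the assignment of such reads is uncertain: WWTR1, AMOTL2, AMOT, TMEM11, CCND2, ICAM1, ELL2, DERL3, BACH2, GPI, COX4I1, RPS9 and the gene with the symbol TAZ.

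**Figure D3:**
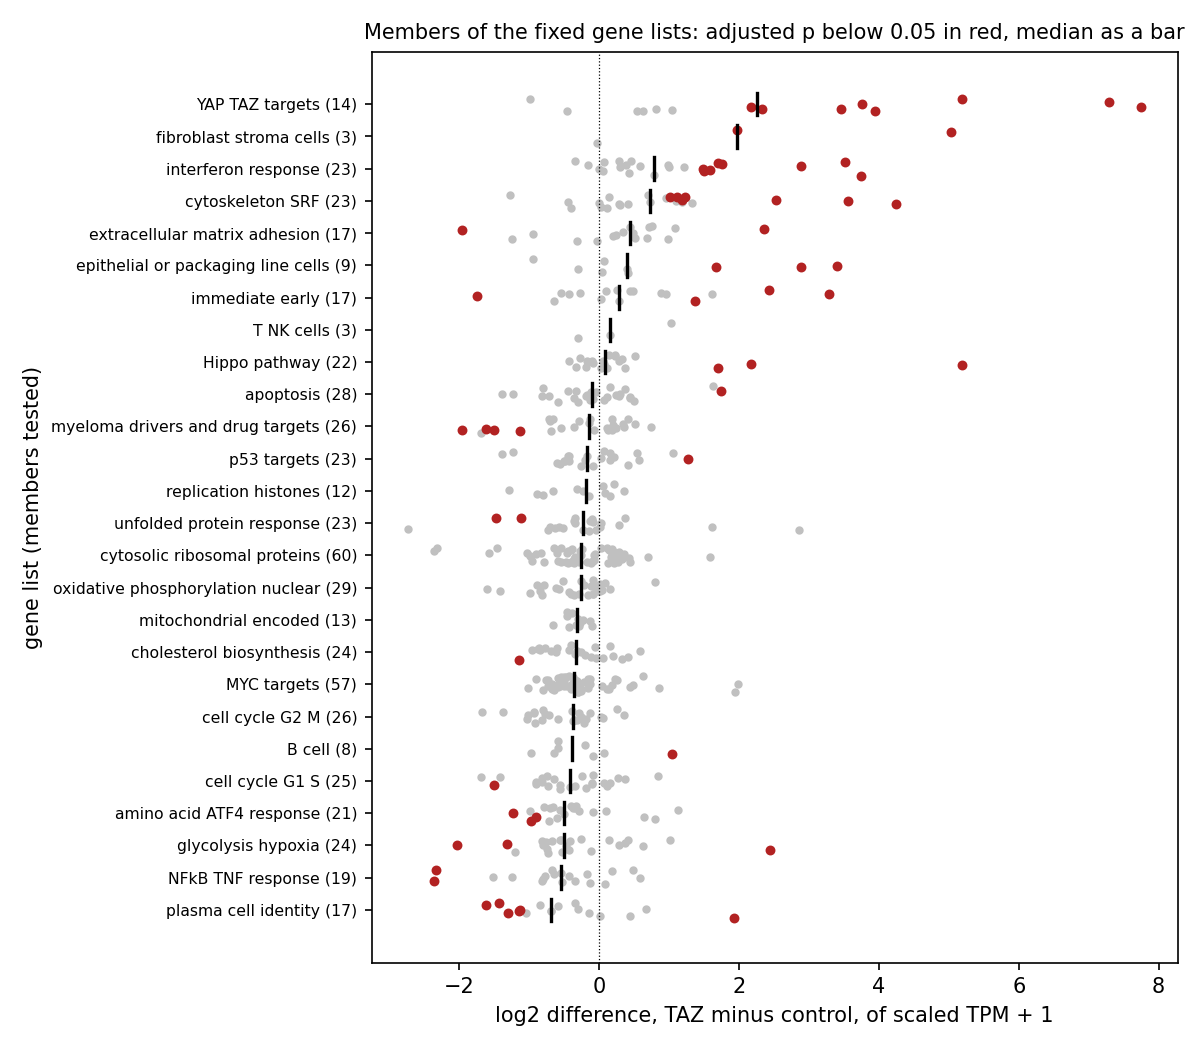
Log2 difference between TAZ and control libraries (x axis, scaled TPM + 1) of each tested member of the 26 lists with at least 3 tested members; red points passed an adjusted p of 0.05 over all tested genes, and the black bar is the median of the list. The medians run from -0.69 for plasma cell identity to 2.25 for YAP and TAZ targets.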

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

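The alternatives that took factors from the tested genes, used cyclic loess or kept only protein-coding genes were chosen after seeing the data. WWTR1 stayed higher and past the threshold in all 18 settings that gave it a value, with log2 differences from 5.78 to 6.85; rescaling without abundant genes removes WWTR1 and gave none. The WWTR1 exon coverage of the coding exons differed between groups by 802 as deposited, by 836 when set to equal depth by aligned bases, and by 471 to 990 with each library left out; exon 1 differed by 0.047 at equal depth and by -0.015 to 0.044. With no filter, 46603 genes were tested, and 352 were called, 290 higher and 62 lower. Without scaling 85 were lower. With each library left out, 270 to 765 genes were called, 220 to 504 higher and 50 to 261 lower, from fewer samples. The low end of 270 was without TAZ library 2, and 349, 337 and 409 were called without control library 2, TAZ library 3 and control library 1. Leaving out a library gave 12 to 20 called lists, with 12 without control library 3. Camera with an estimated correlation called 1 list. The mitochondrially encoded list turned to a median of 0.080 with quantile normalization and 0.057 with cyclic loess; the cause was not tested.

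Of 62 called named genes, 33 were called in every alternative, 40 without each library, and all 62 kept their direction; of 55 not called, 10 were called in some alternative. Of 19 called lists, 11 were called in every alternative that refitted the genes and 18 kept the direction of their camera test, although the median of the unfolded protein response turned to 0.027 without scaling; 2 of the 7 lists not called became called in some. With the replicate number as a block, 236 genes were called, 202 higher and 34 lower, of which 234 were among the 623, and 17 lists. Deviations of libraries with the same number correlated at 0.00, -0.02 and -0.05. They thus showed no shared effect of the number, but with 3 libraries per group a shared day or chip cannot be excluded. With 3 against 3 libraries, 15% of 2-fold changes simulated in the more abundant genes were recovered.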

Other observations

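The gene groups and single genes in the next 2 paragraphs, and the tests on group differences in exon coverage, on fibroblasts and on a small share of epithelial cells, were chosen only after values were seen; the other tests were set before their result was seen.

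Of 19 tested gene entries of antigen presentation by MHC class I, 8 rose and 0 fell (limma, Benjamini-Hochberg; not tested as a group), with a median log2 difference of 1.22 that lay between 1.19 and 1.47 under other scalings; leaving out libraries and other settings gave 1 to 13 calls. The peptide transporter TAP1 went from 95.2 ± 9.004 to 438 ± 32.3 scaled TPM, the immunoproteasome subunit PSMB9 from 47.9 ± 18.4 to 190 ± 41.2, the class I gene HLA-E from 104 ± 12.5 to 290 ± 61.5 and the class I transactivator NLRC5 from 9.39 ± 3.12 to 36.5 ± 2.93. B2M, the light chain of class I molecules, was 622 ± 252 and 1640 ± 206 (adjusted p = 0.0935). None of 12 tested class II entries passed, and their median was -0.39. Genes of 2 checkpoint ligands and of the guanylate-binding protein GBP1, which interferon induces, also rose: CD274 (PD-L1) from 0.497 ± 0.0516 to 9.86 ± 0.553, PDCD1LG2 (PD-L2) from 0.283 ± 0.0821 to 20.8 ± 3.00 and GBP1 from 0.663 ± 0.189 to 24.6 ± 7.66, each called in 19 of 19 other settings. CD47, the signal that blocks phagocytosis, rose from 15.7 ± 2.31 to 40.4 ± 3.11.

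Of 39 tested immunoglobulin gene segments and constant regions, which were not tested as a group, 8 fell and 0 rose, with a median log2 difference of -0.48 that was -0.22 at its smallest under other scalings; 1 to 8 were called in other settings. The kappa constant region IGKC went from 19123 ± 5950 to 5217 ± 1180 scaled TPM (adjusted p = 0.0240, called in 9 of 17 other settings), and the heavy chain segment IGHV1-69 from 138 ± 21.1 to 38.7 ± 8.10. The immunoglobulin share of all TPM was 3.79% ± 0.836 in the controls and 1.82% ± 0.0933 in the TAZ libraries (n = 3; exact permutation p = 0.1, the smallest possible). CXCR4, a chemokine receptor that holds plasma cells in bone marrow, fell from 33.9 ± 11.8 to 5.60 ± 0.825, and ANXA1, a phospholipid-binding protein, rose from 1.32 ± 0.121 to 57.0 ± 3.30.

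The rise of interferon-stimulated genes was weighed against the scaling and against an interferon gene. Scaling argues against itself as the whole cause, since the list's median log2 difference was still 0.68 at its lowest over 5 other scalings of TPM and 0.56 with FPKM. The 9 interferon genes examined were IFNG, IFNB1, IFNE, IFNK, IFNW1, IFNL1, IFNL4, IFNA5 and IFNA6. Other interferon alpha and lambda genes were not found by symbol, so their levels are not known. Of the 9, IFNG was the sole one abundant enough to be tested, through the TAZ libraries alone, and it rose. It averaged 4.90 ± 0.590 scaled TPM in the TAZ libraries and 0.136 ± 0.143 in the controls (limma adjusted p = 0.00187). The highest value of the others among the 9 in a TAZ library was 0.130. Interferon gamma made by the cells may thus contribute, as a hypothesis, and IRF1, GBP1 and TAP1 are among its known targets. Against a full response to it, CXCL10 fell. CIITA and HLA-DRA, which it induces in many cells, were not called in either direction. CIITA was 9.03 ± 2.35 in the controls and 5.61 ± 0.816 in the TAZ libraries (limma adjusted p = 0.259). HLA-DRA was 161 ± 46.0 and 80.1 ± 0.722 (adjusted p = 0.0846). Whether KMM1 cells induce these 2 genes in response to interferon gamma was not tested. A direct effect of TAZ on these genes stays open, as untested.

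The rise of stromal and epithelial markers was weighed against other cells in the TAZ cultures. Fibroblasts would bring abundant collagen, and COL1A1, COL1A2 and COL3A1 reached at most 5.17% of the LUM level in any TAZ library. COL1A1 was 1.79 ± 0.320 in controls and 1.73 ± 0.220 in TAZ libraries. COL1A2 (0.0699 ± 0.0586 and 0.775 ± 0.222) and COL3A1 (0.0512 ± 0.00726 and 0.396 ± 0.0721) were higher in the TAZ libraries but too low to be tested. Short exons held little coverage in all libraries, and the exon lengths of these genes were not compared. The ratio to LUM therefore cannot decide on fibroblasts. Epithelial cells would bring EPCAM and CDH1 with the keratins, yet the highest change of either in a TAZ library was -0.00887% of the rise of KRT8. Both genes were below their control mean in each TAZ library, though EPCAM ran from 22.5 to 73.7 in the controls. Their exon lengths were not compared with those of KRT8 either, and KRT8 has 50 pseudogenes that may share its reads. The ratio to KRT8 therefore cannot decide on epithelial cells that carry EPCAM and CDH1. It does not bear on cells that lack these genes, and packaging line cells were not tested apart. A small share of epithelial cells stays open for KRT18, KRT80 and CLDN4. The controls held EPCAM at 53.3 ± 27.1 and CDH1 at 48.7 ± 10.5 scaled TPM. The lower SD is 52.6% of the largest rise of these 3 genes, enough to hide such a share. A change within the KMM1 cells stays open too, as untested.

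The deposited coverage was uneven along transcripts, and this was weighed against loss of reads that cross exon junctions. The share of internal exons with a depth under 5% of their transcript was at least 3.90 times as high for exons of 100 bases or fewer as for those of 300 bases or more in every library, which is consistent with such loss and could explain the WWTR1 exons listed at 0. The share over internal exons of any length differed between groups by -0.739 percentage points. The ranges overlapped, at 47.4% to 53.4% in the controls and 49.6% to 50.1% in the TAZ libraries. Such a share over a whole library cannot show whether the loss differs between groups for single genes. Of 56 called processed pseudogenes with a tested parent gene, 96.4% changed in the parent's direction, against 57.9% of 1850 tested, so these calls may hold reads of the parents. For 37 of the 56 the parent was the same gene, KRT8, so they are not separate evidence. Of the other 19, 17 followed their parent.

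Across the 10 ways to split the 6 libraries into 3 and 3, the real split gave 623 genes and 19 lists, as many as 1 split (the real one). The highest of the others gave 8 genes and 8 lists. Every other split mixes TAZ and control libraries, so their difference adds to the spread within each part and lowers the calls. The low counts are thus no measure of calls by chance, and 10 splits are too few for a share under 0.05. Among 380 tests of shared name stems with direction, over 190 stems, 1 passed (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0119): keratins, with 4 of 8 tested genes higher (KRT18, KRT5, KRT8 and KRT80). KRT80 went from 0.281 ± 0.0783 to 20.2 ± 3.46 scaled TPM and KRT5 from 0.0239 ± 0.0205 to 1.80 ± 0.390. KRT18, KRT80 and KRT5 were abundant enough to be tested only through the TAZ libraries. The rise itself thus set part of the 8 tested genes, which weakens this test. KRT18 and KRT80 were called in 19 of 19 other settings, KRT8 in 15 of 19 and KRT5 in 13 of 18.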
